A study of Mus musculus with 6 samples.

How the data were processed

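The series holds 6 Affymetrix arrays of RNA pools from the mouse line VOT-E36, 1 for proliferating conditions and 1 for each of days 1, 2, 4, 7 and 14 in differentiating conditions. Per the labels' protocols, biotin-labelled cRNA was made from 6 µg of total RNA by the manufacturer's standard method. Groups were taken from the time point given with each sample. The titles, source names and characteristics of all 6 samples name the cell line, while their description fields name 4 cochleas dissected from embryos; the former were followed. The labels give no day for proliferating cells, which were coded as day 0. The labels say that the cultured cells were of the same passage, and nothing says that pools came from separate experiments.

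The deposited values are 1 log2 level per probe set and array, running from −14.9 to 13.6. That the base is 2 was taken from the values, since the top values on another base would exceed what a 16-bit scanner records. The software for background correction, summarization and normalization is not given in the sources used here. The distributions of the 6 arrays were not identical, so quantile normalization at the probe set level had not been applied, and the medians ran from 5.28 to 6.19. Values run far below 0, so the log2 differences of dim genes are large and noisy. A floor of detection of 4.39 was set after seeing the data at the highest value of 19 control probe sets for bacterial and yeast transcripts over the 6 arrays. By this floor 2149 genes (26.0%) were undetected on all arrays. Where a gene was at or below it on one side of a comparison, the text gives a bound ("at least N-fold") from means of log2 values in which lower values were set to the floor, while the test used the values as deposited. For a rise between conditions, a bound is given only where the gene was above the floor on all 5 differentiating arrays.

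Of 12488 probe sets, 10855 had 1 gene symbol in the platform annotation, 396 had several and 1237 had none, and 10839 matched a RefSeq gene table by gene identifier, with 0 symbols changed. The platform annotation may be old. A gene with several probe sets (2076 of 8252 genes) was represented by the one with the highest mean level. Among 134 genes picked out by the naming rule, 26 had a further probe set above the floor, and in 5 of these (Ifi204, Hspa4, Rbmx, Cox6c and Mbp) one or more further probe sets changed in the opposite direction on the mean of the 5 differentiating arrays.

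Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the 8252 genes and a threshold of 0.05. Gene levels were fitted in 3 ways: a slope on log2(day + 1) over all 6 arrays, the mean of the 5 differentiating arrays minus the proliferating array, and a slope on log2(day) over the 5 differentiating arrays. The residual degrees of freedom were 4, 4 and 3. Slopes are printed as the fitted log2 change over the whole span with its SE. With an array left out, the slope was still multiplied by that whole span. Without the first or last array it is therefore extrapolated. In the second fit the lone proliferating array is assumed to vary like the other 5, whose spread includes real change over days. The prior degrees of freedom were 13.9 in the first fit, 11.9 in the second and infinite in the third, where every gene of a given level is given the same variance. The standard errors are those of the moderated fit. Precision is limited by the number of arrays.

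Before the data were examined, 27 gene lists were written from general knowledge, with 1026 members of which 800 were measured. They cover mitosis and cytokinesis, DNA replication and S phase, p53 targets, the interferon response, heat shock and chaperones, cold-inducible genes, endoplasmic reticulum stress and the amino acid response, hair cells, supporting and prosensory cells, otic vesicle regulators, neurons, epithelium, mesenchyme and matrix, the insulin-like growth factor pathway, sterol and fatty acid synthesis, ribosome biogenesis and Myc targets, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, lysosome, inflammatory and secreted factors, immediate early genes, and erythroid, immune, endothelial, glial and neural crest, and muscle cells. Each was tested with limma's camera (preset inter-gene correlation 0.01) in the 3 fits, adjusted over the lists within a fit, and again with an estimated correlation, under which 0 lists passed in any fit. Camera ranks a list against all genes, whose median fitted change was −0.28 in the first fit, 0.06 in the second and −0.45 in the third. Its direction differed from the sign of the list's own median or mean in 8, 4 and 11 lists, of which 0 passed. The median change of each list on each day was set against 10000 random lists of the same size, matched on mean level in 10 bins, as a description of these arrays.

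The designs, lists, most alternatives and the rule for named genes were also fixed before that point. Among the 5392 genes whose highest value exceeded the median of all probe set values (5.56), the rule took the 10 largest rising and falling slopes past the threshold over the whole course, the 10 genes in each direction with the largest smallest difference of the 5 differentiating arrays from the proliferating array, the 5 largest slopes in each direction within the differentiating days, the 5 largest early transient gaps in each direction, and up to 4 members of each list with the largest mean difference between conditions. Dlx5, Polk, Cdkn1a, Epyc, Lfng, Ifit3, Ckap2, Bhlhe40, Ctsa, Gaa, Neu1, Ncl, Nop58, Cad, Nme2, Lcn2, Serpina3n, Cxcl12, Igf2, Igfbp2 and Igfbp4 were named after their values were seen. The rule ranked the values as deposited, also those below the floor, so it picks genes to name and does not order the sizes of their changes.

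The fits were tested on simulated arrays of 8252 genes with the estimated variances, in which 200 genes were changed. At a true log2 change of 4, the slope over the whole course recovered 75.0% of the changed genes, the contrast of conditions 77.0% and the slope within differentiating days 78.0%; at a change of 2 they recovered 22.0%, 20.0% and 40.0%. The share of false calls was 7.62%, 4.90% and 2.48%. The simulated noise was independent between genes, and the simulated arrays did not differ in brightness. These shares therefore do not cover correlated genes or the differences in brightness of the real arrays. The simulated variances were drawn from each fit's own prior, so the shares cannot show whether that prior holds. In the third fit, genes of a given level were simulated with nearly the same variance, as the fit itself assumes. Alternatives were quantile normalization, centring of arrays on the median, filters on dim genes, the mean of a gene's probe sets, every probe set tested, eBayes without a trend or robust, other codings of time, and each array left out. Chosen after seeing the data were the floor for low values, centring on the 9 spike-in probe sets, and other scalings for early transient genes, median centring together with the floor among them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.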

Results

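Gene expression was measured in VOT-E36 cells, an epithelial line derived from the ventral otocyst, the rudiment of the inner ear, of mouse embryos at embryonic day 10.5. The line carries a temperature-sensitive form of the viral T antigen (tsA58), which keeps cells dividing and binds p53, under a promoter that gamma-interferon switches on. Proliferating cells were kept at 33 °C with gamma-interferon, and differentiating cells at 39 °C without it. RNA pools came from proliferating cells and from cells after 1, 2, 4, 7 and 14 days in differentiating conditions, with 1 array for each of the 6 states. The labels place the cultures in the same passage. No state has a replicate, so differences between pairs of arrays have no replicate check. The p-values of single genes below measure only the scatter of these arrays around a fitted course. That scatter was shared in part, and in the third fit wholly, over genes of similar level. The p-values of gene lists rank their members against other genes and do not measure differences between cultures either. Of the 12488 probe sets, 10855 had a single gene symbol and stood for 8252 genes. Between 65.5% and 72.0% of these genes lay above a log2 level of 4.39 on each array, the highest value of 19 control probe sets for bacterial and yeast transcripts, which was taken as the floor of detection.

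The arrays differed in overall brightness. Relative to the proliferating array, the median gene differed by 0.02 on the log2 scale on day 1, 0.60 on day 2, 0.13 on day 4, −0.18 on day 7 and −0.16 on day 14. The 9 spike-in probe sets, for transcripts added to the labelled samples, were higher by 0.74 (SD over probe sets 0.11) on day 2 and by 0.59 (SD 0.17) on day 4. Changes of gene lists on single days are therefore given relative to the median gene. The choice matters on day 4, where the spike-ins rose more than the median gene. The median change of the DNA replication list on day 4 was 0.26, above the median gene but below the spike-ins. Across probe sets, which are not independent replicates, the Spearman correlation with the proliferating array was 0.971 on day 1, 0.950 on day 4 and 0.936 on day 14.

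**Figure D1:**
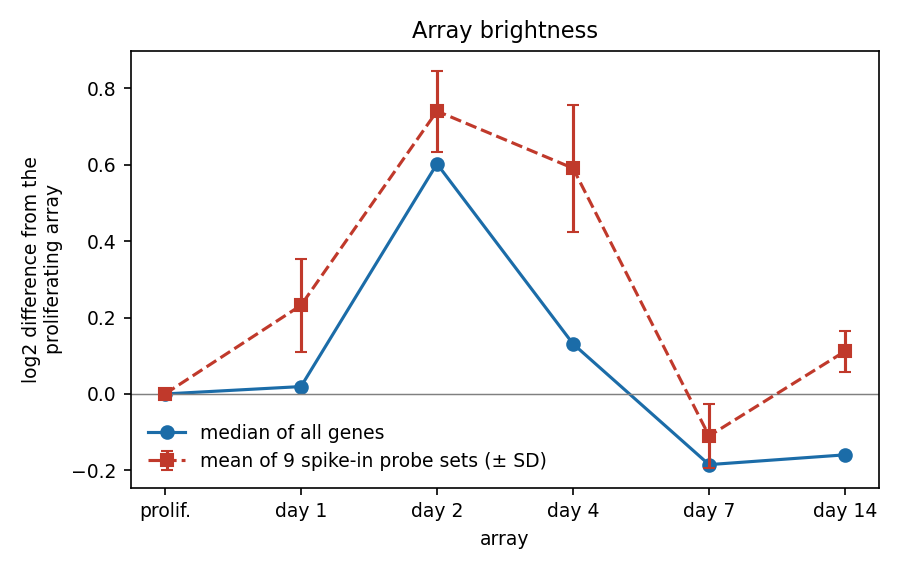
Log2 difference of each array (x axis) from the proliferating array (y axis), as the median of all genes (circles) and the mean of 9 spike-in probe sets (squares, with the SD over probe sets). Both were highest on day 2, at 0.60 and 0.74.

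The first comparison set the 5 differentiating arrays against the proliferating array, the step at which the labels place the arrest of growth. The proliferating state has 1 array, whose variance was taken from the 5 differentiating arrays, so its own spread was not measured. Among p53 targets, 6 of 25 genes rose. Sesn1, an inhibitor of growth signalling through mTORC1, stood at 3.62 on the proliferating array. It lay between 7.38 and 8.85 on the 5 differentiating days, a rise of at least 13.0-fold. The death receptor gene Fas rose at least 8.52-fold, and the growth-restraining genes Ddit4 and Btg2 rose by 3.27 ± 0.47 and 3.14 ± 0.46 (log2 change ± SE). The others were Cdkn1a and Polk, named after their values were seen, Polk being above the floor on 2 of the 5 days. These 6 passed on the values as deposited, and none of them with low values set to the floor. None of the list fell, and 14 rose when p was adjusted over the list alone. Relative to the median gene, the list's median was 1.19 higher on day 1, 1.80 on day 4 and 1.37 on day 14, above that of every one of 10000 random lists of matched level on each day. The list passed the camera test (adjusted p = 4.59e-10; adjusted p = 0.939 with an estimated correlation).

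In the interferon-response list 8 of 46 genes fell, and in the list of ribosome biogenesis and Myc targets 1 of 41. Isg15, a ubiquitin-like antiviral protein, fell by 3.68 ± 0.66 and the interferon-induced gene Ifi204 fell by 2.46 ± 0.50, although a second Ifi204 probe set was higher by 0.74. Socs1, an inhibitor of cytokine signalling, stood at 9.37 on the proliferating array and fell at least 15.5-fold, and the antiviral gene Rsad2, which was not in the list, went from 5.84 to below the floor on all 5 days, at least 2.73-fold lower (adjusted p = 0.00275). In the interferon-response list 0 genes rose, and 16 were lower when adjusted over the list alone (camera adjusted p = 2.04e-12; adjusted p = 0.939 with an estimated correlation). Their median relative to all genes was −0.78 on day 1 and −1.80 on day 14. With low values set to the floor, Isg15, Ifi204 and Socs1 did not pass. In the list of ribosome biogenesis and Myc targets, Srm, which makes spermidine, fell by 1.99 ± 0.47 and was the only 1 of 41 to pass, with 7 lower when adjusted over the list alone. Myc itself differed by −1.94 ± 0.58 and did not pass (adjusted p = 0.134). The list's camera adjusted p was 7.87e-12, and its adjusted p = 0.939 with an estimated correlation.

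Of 39 lysosomal genes 4 rose, and of 31 genes of the supporting cell and prosensory list 2. Tpp1, a lysosomal peptidase, rose by 2.27 ± 0.47, Hexa by 2.55 ± 0.51 and Arsa by 3.44 ± 0.49, and the cathepsin gene Ctsf rose at least 5.85-fold. None of the lysosomal genes fell, and 6 were higher when adjusted over the list alone (camera adjusted p = 7.10e-07; adjusted p = 0.942 with an estimated correlation). In the supporting cell and prosensory list, the receptor genes Notch1 and Notch3 rose, by 3.78 ± 0.50 and at least 17.6-fold, and 3 were higher when adjusted over the list alone. Hes6 differed by 1.74 ± 0.52 (adjusted p = 0.134). The list passed camera (adjusted p = 0.0158; adjusted p = 0.942 with an estimated correlation), but not with each gene's probe sets averaged (adjusted p = 0.0528). The immediate early list ranked above other genes (adjusted p = 0.0256; adjusted p = 0.989 with an estimated correlation), with Egr1 and Btg2 the 2 of 24 genes past the threshold, and 4 higher and 1 lower when adjusted over the list alone. It did not pass without the day 4 array (adjusted p = 0.0709) or the day 14 array (adjusted p = 0.0670), nor with probe sets averaged (adjusted p = 0.129). Sterol and fatty acid synthesis ranked below other genes as a list of 24 with 0 past the threshold, over all genes or over the list alone (camera adjusted p = 0.0131; adjusted p = 0.989 with an estimated correlation; adjusted p = 0.0578 among the brighter genes). The 38 mitosis genes also passed camera downward, with 0 members past the threshold (adjusted p = 0.00273; adjusted p = 0.989 with an estimated correlation), and did not pass once arrays were centred on their medians (adjusted p = 0.0815) or on the spike-ins (adjusted p = 0.162).

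Several genes went from below the floor in proliferating cells to above it on all 5 days. Mgp, an inhibitor of calcification in the matrix, stood at 1.38 on the proliferating array and at 7.16 to 9.57 on the 5 differentiating arrays, at least 21.8-fold higher. Stard10, a lipid-transfer protein, rose at least 15.3-fold, and Tnfrsf18, a receptor of the tumour necrosis factor family, at least 9.22-fold. The peptidase gene Anpep, the chemokine gene Cxcl1 and the calcium sensor gene Vsnl1 rose at least 8.26-fold, 8.02-fold and 7.45-fold. These genes passed on the values as deposited, but not with low values set to the floor. The same held for Scg2, a protein of secretory granules, the integrin gene Itgb4, Ces2g and Pam. Those were above the floor on 4, 4, 4 and 3 of the 5 days, so no mean fold is given. Their highest levels were 10.47, 8.12, 7.56 and 6.33. The homeobox genes Dlx1 and Dlx5, above the floor on 4 and 3 of the days and at 7.46 and 5.35 on day 2, passed upward as 2 of 37 genes of the otic vesicle list (also 2 when adjusted over the list alone), which did not pass as a list (adjusted p = 0.401). The matrix gene Dcn rose by 3.18 ± 0.72 and Postn rose at least 8.33-fold. On the falling side, the adhesion protein gene Cxadr was at least 5.35-fold lower, Mpeg1 at least 19.3-fold, Cyp4a12b at least 10.0-fold and Gm9706 at least 12.4-fold. Il18bp (adjusted p = 0.101) and Sh3bp5 (adjusted p = 0.103) were lower on all 5 days without passing.

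In all, 144 of the 8252 genes passed limma's test at an adjusted p of 0.05, 124 higher and 20 lower in differentiating conditions. With each array centred on its median, 384 passed, 227 higher and 157 lower, and 121 of these were among the 144; with quantile normalization 250 were higher and 126 lower, and with the spike-ins 202 and 274. With low values set to the floor 15 passed, 1 higher and 14 lower, and 5 of these were among the 144. Of 40 named genes that passed, 10 still did with no variance trend, 3 with low values set to the floor, 30 with a robust prior (not Tnfrsf18, Itgb4, Socs1, Ces2g, Scg2, Mpeg1, Gm9706, Dlx1, Dcn and Postn), 30 with averaged probe sets (not Egr1, Hexa, Ifi204, Mpeg1, Srm, Polk, Rpl22, Mef2a, Dlx1 and Dcn), and 32 with median centring, which ended the calls of Scg2, Cxadr, Mpeg1, Dlx1, Postn, Dcn, Hexa and Mef2a. Without the day 2 array, Cyp4a12b, Tpp1, Socs1, Rpl22, Hexa, Gm9706, Mpeg1, Scg2, Polk, Dlx5, Mef2a, Dlx1, Postn and Dcn did not pass (adjusted p from 0.0502 to 0.167). Srm did not pass without day 1 (adjusted p = 0.0537), nor did Ccl2, Mef2a and Srm without day 4 (adjusted p from 0.0605 to 0.0697). The count of all genes was 74 without the day 2 array, 277 without day 14 and 221 without day 7.

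The second comparison asked which genes had a slope on the logarithm of the day from proliferating cells through day 14. Such a slope can also come from a single step between conditions or from a late change, so it does not show a steady course. Of 38 genes of mitosis and cytokinesis, 30 fell. Kif20a, a kinesin of cytokinesis, stood at 9.30 in proliferating cells, 9.64 on day 2 and 5.38 on day 7, and was below the floor on day 14, at least 30.0-fold lower than at the start. Top2a, Aurkb and Aspm fell at least 22.2-fold, 7.62-fold and 3.01-fold over the same span, and the kinase gene Plk1, above the floor throughout, fell by 4.17 ± 0.62 over the fitted course. Of the mitosis genes 0 rose, and 36 fell when adjusted over the list alone (camera adjusted p = 8.51e-21; adjusted p = 0.829 with an estimated correlation). Relative to all genes the list's median was 0.23 on day 1, −0.17 on day 2, −0.68 on day 4, −1.88 on day 7 and −2.91 on day 14. Of 47 genes of DNA replication and S phase 10 fell, and the list's median relative to all genes was 0.13 on day 4, −0.41 on day 7 and −0.996 on day 14. Rrm2, a subunit of ribonucleotide reductase, fell by 3.72 ± 0.67, Ccne1 fell by 3.05 ± 0.61 and Cdc45 fell at least 8.01-fold, with 14 members lower when adjusted over the list alone (camera adjusted p = 1.18e-06; adjusted p = 0.829 with an estimated correlation; adjusted p = 0.204 without the day 14 array).

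**Figure D2:**
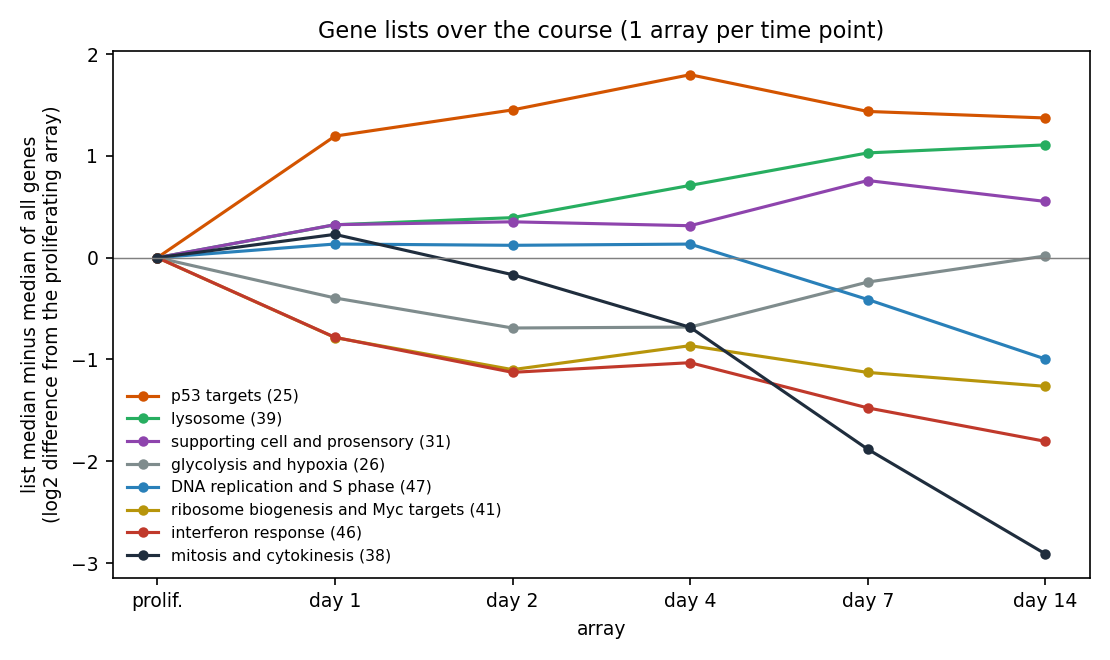
Median of 8 gene lists (number of measured genes in parentheses) on each array (x axis), as the log2 difference from the proliferating array minus that of the median gene (y axis), with 1 array per time point. The p53 list was at 1.19 on day 1, while the mitosis list was at 0.23 on day 1 and −2.91 on day 14.

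Of 46 interferon-response genes 20 fell over the course. The transcription factor gene Irf8 stood at 9.13 in proliferating cells, 6.92 on day 1 and 4.03 on day 14, at least 26.7-fold lower. Isg15 fell by 4.41 ± 0.63 over the fitted course (−2.93 without the proliferating array, extrapolated to the same span). The chemokine gene Cxcl10 fell at least 4.17-fold, and outside the list the interleukin-18 inhibitor gene Il18bp fell at least 20.5-fold. None of the list members rose, and 25 were lower when adjusted over the list alone (camera adjusted p = 7.06e-12; adjusted p = 0.829 with an estimated correlation). Of 41 genes of ribosome biogenesis and Myc targets 5 (Srm, and by values seen afterwards Ncl, Nop58, Cad and Nme2) fell and 0 rose, with 17 lower when adjusted over the list alone (adjusted p = 7.06e-08; adjusted p = 0.829 with an estimated correlation; adjusted p = 0.151 without the proliferating array). In the sterol and fatty acid list, Fdps fell by 1.88 ± 0.43 as the only 1 of 24 to pass, with 9 lower when adjusted over the list alone (adjusted p = 0.00258; adjusted p = 0.829 with an estimated correlation; adjusted p = 0.143 without the proliferating array; adjusted p = 0.212 among the brighter genes). Oxidative phosphorylation passed downward as a list of 45 with 0 single genes (adjusted p = 0.0384; adjusted p = 0.829 with an estimated correlation), and lost that call under 9 further settings, quantile normalization among them (adjusted p = 0.0727).

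Of 39 lysosomal genes 5 rose, with Hexa higher by 2.94 ± 0.53 and Arsa by 2.95 ± 0.80. Without the proliferating array these changes, extrapolated to the same span, were 1.82 (adjusted p = 0.0765) and 0.53 (adjusted p = 0.783). The others were Ctsa, Gaa and Neu1, named after their values were seen, and 0 fell, with 13 higher when adjusted over the list alone (camera adjusted p = 8.26e-10; adjusted p = 0.829 with an estimated correlation). The list's median relative to all genes was 0.32 on day 1, 0.71 on day 4 and 1.11 on day 14. In the supporting cell and prosensory list S100a1, a calcium-binding protein, rose by 3.71 ± 0.58. The other members past the threshold, Epyc (higher) and Lfng (lower), were named after their values were seen, and the counts were the same when adjusted over the list alone. The list passed upward (adjusted p = 0.0170; adjusted p = 0.829 with an estimated correlation), but not without the proliferating array (adjusted p = 0.219) or the day 14 array (adjusted p = 0.0594), nor with probe sets averaged (adjusted p = 0.0723). The p53 list passed upward (adjusted p = 0.000592; adjusted p = 0.829 with an estimated correlation) with Btg2 alone of 25 past the threshold, and 5 higher and 1 lower when adjusted over the list alone. Without the proliferating array its median relative to all genes was −0.19 (adjusted p = 0.979), while without any other single array it was between 1.02 and 1.95. The immediate early list passed upward (adjusted p = 0.0204; adjusted p = 0.829 with an estimated correlation; adjusted p = 0.191 without the proliferating array; adjusted p = 0.0931 with probe sets averaged), with Btg2 higher and Fosl1 lower, and 2 higher and 1 lower when adjusted over the list alone.

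Several rising genes were below the floor in proliferating cells. Scg2 reached 10.47 on day 14, at least 67.4-fold above the start, and the matrix gene Mgp 9.12, at least 26.5-fold. The carboxylesterase gene Ces1d passed the floor only on day 14, at 8.27 (at least 14.7-fold), and it did not pass without that array (adjusted p = 0.0825). Plin4, which coats lipid droplets, rose at least 8.12-fold, Gm4788 at least 6.62-fold, the sialyltransferase gene St6galnac5 at least 5.39-fold, Rnase1 at least 3.83-fold (adjusted p = 0.308 without the day 14 array), and Itgb4, Cfhr2 and Aebp1 at least 2.59-fold, 2.54-fold and 2.19-fold. Among falling genes, the mesothelial surface protein gene Msln went from 8.60 to 4.04 on day 2 and stayed below the floor, at least 18.4-fold lower. Tagln, which binds actin, fell at least 20.0-fold, Dbn1 at least 2.57-fold, and Haspin, Psmc3ip and Spag5 at least 1.54-fold, 1.80-fold and 1.22-fold. In the neuronal list Eno2 rose by 3.39 ± 0.61 beside Scg2, while Uchl1 fell at least 1.97-fold; the list of 40 did not pass (adjusted p = 0.110), and the same counts of 2 and 1 passed when adjusted over the list alone. Stmn2 of that list differed by 1.13 ± 0.72 (adjusted p = 0.488), and by −0.35 with its probe sets averaged.

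**Figure D3:**
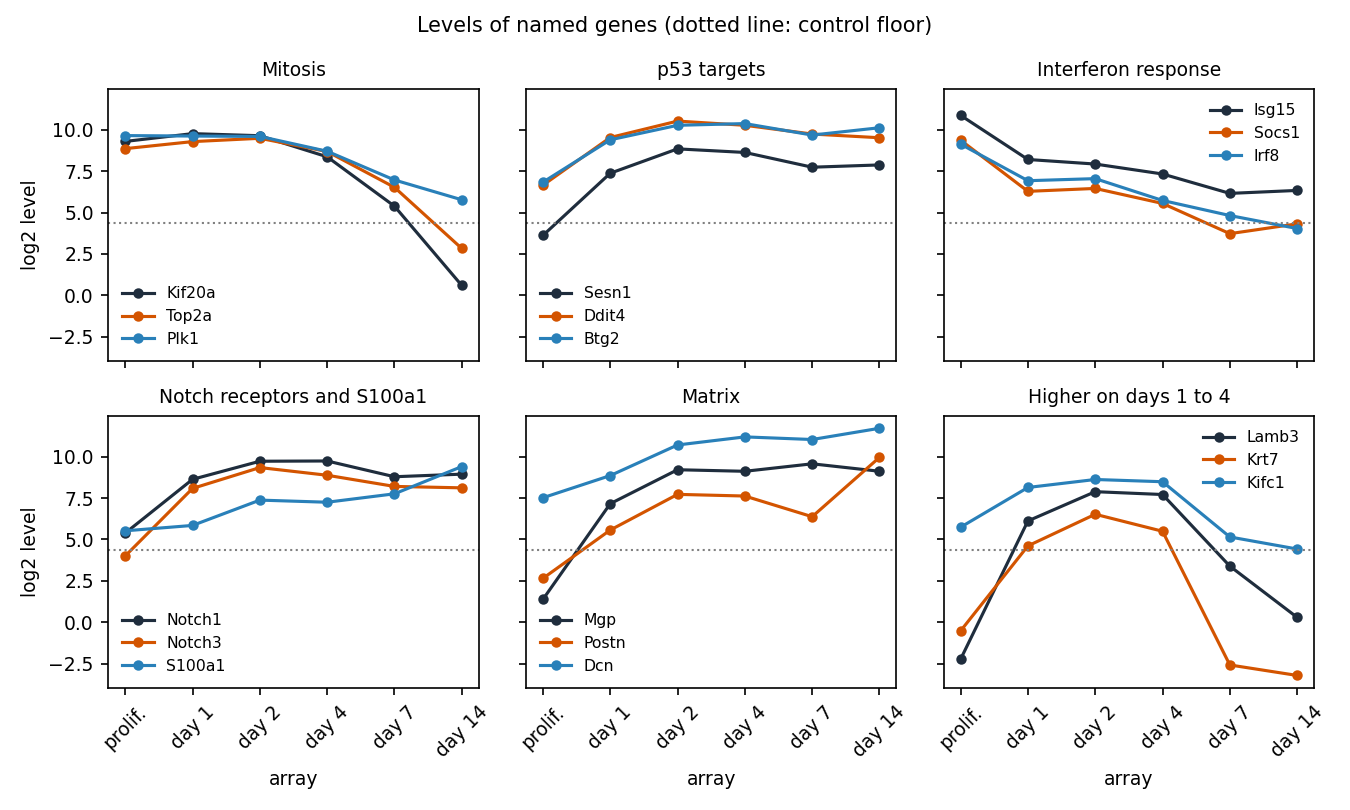
Log2 levels (y axis) of 18 named genes on the 6 arrays (x axis), 1 line per gene, with the control floor of 4.39 as a dotted line. Kif20a, Top2a and Plk1 lay between 8.37 and 9.77 up to day 4, while Sesn1, Ddit4 and Btg2 were higher from day 1.

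In all, 346 genes passed, 103 higher and 243 lower, of which 197 were above the floor on all 6 arrays. With arrays centred on the median 461 were higher and 637 lower, with quantile normalization 587 and 577, and with the spike-ins 380 and 795. Of 54 named genes that passed, 47 did so with median centring (Rnase1, Itgb4, Epyc, Igfbp2, Ncl, Nme2 and Srm did not), 18 with low values set to the floor, and 1 (Msln) with no variance trend. A robust prior ended 19 of these calls, among them Kif20a (adjusted p = 0.205), Aurkb (0.216), Top2a (0.266), Aspm (0.269), Mgp (0.312) and Scg2 (0.0625). The day on a linear scale ended 18, among them Mgp (0.217) and Hexa (0.0745), and averaged probe sets 16, among them S100a1 (0.777), Fdps (0.374) and Hexa (0.117). Without the proliferating array Neu1, Aebp1, Hexa, Fdps, Cct3, Nme2, Nop58, Akt2, Gaa, Mef2a, Ncl, Itgb4, Srm, Arsa and Btg2 did not pass (adjusted p from 0.0512 to 0.804). Without day 14 this held for Igfbp2, Fosl1, Fdps, Ncl, Cad, Nme2, Ces1d, Ddit3, Spag5, Gaa, Ccne1, Neu1, Psmc3ip, Rnase1, Nop58, Lfng, Epyc, Igf2 and Cdc45 (from 0.0546 to 0.678). Without day 1 it held for Arsa, Igf2, Ddit3, Neu1, Rnase1, Fdps, Mef2a, Nop58, Cad, Lfng, Igfbp2, Uchl1, Nme2, Epyc and Gaa (from 0.0517 to 0.149). Day 2 decided Igf2, Cdc45, Cad, Epyc, Rnase1 and Igfbp2 (from 0.0512 to 0.0679 without it). Day 7 decided Uchl1, Cad, Gaa, Ncl, Nme2, Srm, Epyc and Nop58 (from 0.0522 to 0.147) and day 4 Gaa (0.0580). The count of all genes was 212 without the day 1 array, and without day 14 it was 284, of which 159 were higher and 125 lower.

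The third comparison took the 5 differentiating arrays alone, which leaves out the step from proliferating cells. No proliferating culture was followed over the same days, so a slow response to the change of conditions cannot be told from time in culture. Of 38 mitosis genes 36 fell (38 when adjusted over the list alone). Over the fitted span from day 1 to day 14 Plk1 fell by 4.14 ± 0.54, while Top2a went from 9.29 on day 1 to below the floor on day 14 (camera adjusted p = 2.59e-35; adjusted p = 0.990 with an estimated correlation). Of 47 DNA replication genes 17 fell, with 31 lower when adjusted over the list alone (adjusted p = 5.42e-10; adjusted p = 0.990 with an estimated correlation; adjusted p = 0.135 without the day 14 array). Of 46 interferon-response genes 15 fell and Ifit3 rose, with 20 lower and 1 higher when adjusted over the list alone (adjusted p = 0.000316; adjusted p = 0.990 with an estimated correlation). The p53 list did not pass (adjusted p = 0.903), with Ckap2 alone of 25 lower, over all genes and over the list alone; its median change was −0.54, while camera ranked it upward against all genes. The keratin gene Krt7 stood at 6.52 on day 2, and the Notch ligand gene Jag2 at 6.12. Both were below the floor on days 7 and 14. Their slopes passed limma's test on the values as deposited (adjusted p = 2.64e-13 and 1.32e-07). With low values set to the floor they did not (adjusted p = 0.647 and 0.743), nor did Jag2 with median centring (adjusted p = 0.144).

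Glycolysis and hypoxia genes ranked above other genes within the differentiating days, with a median fitted change of 0.01 over the 26 members against −0.45 over all genes (camera adjusted p = 0.00336; adjusted p = 0.990 with an estimated correlation; adjusted p = 0.393 without the day 14 array). Hk2, which phosphorylates glucose, stood at 6.84 in proliferating cells, 2.04 on day 4 and 6.93 on day 14. It rose with Bhlhe40 as the 2 members past the threshold, also when adjusted over the list alone. With its probe sets averaged, the change of Hk2 was 1.05 and did not pass limma's test (adjusted p = 0.780). Relative to all genes the list's median was −0.69 on day 2 and 0.02 on day 14. Lysosomal genes ranked above other genes (adjusted p = 2.31e-05; adjusted p = 0.990 with an estimated correlation), with a median change of 0.38 and Ctsa alone of 39 past the threshold and 3 when adjusted over the list alone. Inflammatory and secreted factors also ranked above other genes, with a median change of 0.01 (adjusted p = 0.00533; adjusted p = 0.990 with an estimated correlation) with Lcn2 and Serpina3n of 38 higher and Ptgs2 and Cxcl12 lower (3 and 2 when adjusted over the list alone), and did not pass with median centring (adjusted p = 0.190), without the day 2 array (adjusted p = 0.0749) or without day 7 (adjusted p = 0.0521). Rnase1, Gm4788, Plin4, Ces1d and Scg2 passed upward within these days and Aspm, Kif20a, Msln, Krt7 and Jag2 downward, with values below the floor on 1 or more of the days, so their sizes are not ordered.

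In all, 410 genes passed within the differentiating days, 66 higher and 344 lower, while median centring gave 385 higher and 551 lower, quantile normalization 545 and 575, and the spike-ins 340 and 594. The fit gave every gene of a given level the same variance, which makes its smallest p-values too firm. With low values set to the floor 0 genes passed limma's test (798 at an unadjusted p under 0.05). The count was 36 without the day 14 array (14 higher and 22 lower), 227 without day 7 and 2151 without day 1 (67 and 2084). Of 25 named genes, 24 passed with median centring (Jag2 did not), 22 with a robust prior (not Kif20a, Igfbp2 and Jag2) and 13 with no variance trend. With averaged probe sets 23 passed (Hk2 and Igf2 did not). Without the day 14 array Top2a, Plk1, Foxm1, Igfbp4, Ptgs2, Ces1d, Cxcl12, Jag2, Bhlhe40, Ckap2, Ctsa, Hk2, Ifit3 and Igf2 did not pass (adjusted p of 0.0606 or more). Ifit3 and Ctsa did not pass without day 4 (0.0727 and 0.194) or day 7 (0.0509 and 0.220), nor Ctsa without day 1 (0.0531).

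Genes higher or lower on both day 1 and day 2 than on the proliferating, day 7 and day 14 arrays were compared by the gap between the 2 sets of arrays, with no test. The kinesin gene Kifc1, above the floor throughout, was at 8.14 and 8.62 on days 1 and 2 and at 5.74 or less on the proliferating, day 7 and day 14 arrays, a gap of 2.40. With low values set to the floor, Lamb3, a laminin chain of the epithelial basement membrane, had a gap of 1.73 and Krt7 one of 0.22. Jag2 and the signalling gene Wnt4 reached 6.12 and 6.02 on day 2 but were below the floor on day 1. In the other direction, again from the floor, the gap was −0.29 for Hk2, −0.42 for Dbndd2, −0.70 for A4galt and −0.51 for Slc4a4. With median centring as well, these gaps were −0.57, −0.58, −0.76 and −1.33, against 2.09 for Kifc1, 1.82 for Lamb3 and 0.32 for Krt7. Rnase1 was below the floor on every array but day 14. Of 5392 genes brighter than the median probe set value on some array, 1696 were higher and 27 lower. With median centring 631 were higher and 733 lower, and with the spike-ins 536 and 768, so the balance differed between scalings. A gap over 1 was seen for 53 higher and 2 lower genes, or 20 and 7 with median centring, 37 and 0 with low values set to the floor, and 16 and 4 with both.

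Of the 27 lists, 15 did not pass in any comparison. Several had few members measured or above the floor, so their not passing says little about those genes. In proliferating cells 8 of 40 neuronal, 5 of 21 immune, 5 of 17 endothelial and 13 of 37 epithelial genes were above the floor. The hair cell list had 43 members, of which 15 were measured. Of 15 hair cell genes measured, 2 were above the floor in proliferating cells and 4 on any array, with the hair cell myosin gene Myo7a at 3.96 in proliferating cells, 6.20 on day 2 and 5.00 on day 14 (adjusted p = 0.412 for the change of conditions). The lowest adjusted p of any comparison was 0.457 for the hair cell list, 0.0538 for the neuronal, 0.109 for the muscle, 0.150 for the glia and neural crest, 0.345 for the endothelial, 0.399 for the erythroid and 0.734 for the immune list. It was 0.256 for epithelial genes, 0.183 for mesenchymal and matrix genes, 0.401 for otic vesicle regulators, 0.246 for the insulin-like growth factor pathway, 0.109 for heat shock and chaperones, 0.177 for the 3 cold-inducible genes, 0.183 for endoplasmic reticulum stress and 0.350 for cytosolic ribosomal proteins. Within these lists, Foxo3 and Mef2a of the insulin-like growth factor pathway rose with the change of conditions, by 2.52 ± 0.47 and 2.28 ± 0.54, as 2 of 25 (4 when adjusted over the list alone). Over the whole course Akt2 rose by 2.29 ± 0.49 and Mef2a by 2.48 ± 0.60. Without the proliferating array these changes, extrapolated to the same span, were 1.43 and 1.34. Foxm1, which drives mitotic genes, fell by 4.01 ± 0.62 over the whole course. Igf2 fell by 2.74 ± 0.67. Extrapolated to the same span, its change was −1.11 without the day 14 array (adjusted p = 0.670) and −4.27 without the proliferating array. Over the span from day 1 to day 14 its fitted change was −3.04. Igfbp2 fell at least 12.5-fold over the whole course (4 higher and 3 lower when adjusted over the list alone). Within the differentiating days 0 rose and Foxm1, Igf2, Igfbp2 and Igfbp4 fell, also when adjusted over the list alone. The ribosomal protein gene Rpl22 rose by 2.68 ± 0.56, while Ddit3, a stress-induced transcription factor, rose by 2.48 ± 0.54 over the whole course and the chaperonin gene Cct3 fell by 1.94 ± 0.44.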

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

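The tests of array brightness, of the small transient set and of cochlear tissue were chosen after the results they bear on were seen, as were the orders of centred arrays once the uncentred counts were known; the other tests were set before their results. Probe sets with no single gene symbol entered no gene-level comparison. Leaving out the manufacturer's control probe sets, 1589 were of this kind, and 18 of them passed limma's test of the change of conditions when every probe set was tested, 16 higher and 2 lower. One of these stood at −0.64 on the proliferating array and at 7.43 to 9.41 on the 5 differentiating arrays, a smallest difference of 8.07 (adjusted p = 1.30e-05). Another went from −0.03 to between 7.55 and 9.51, a smallest difference of 7.58 (adjusted p = 1.64e-05). Both starting values lie below the floor, so these rises are at least those from 4.39. The pair that fell was lower on every differentiating array, with smallest differences of −1.94 and −1.47 (adjusted p = 0.0143 and 0.0372).

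Array order was shuffled to see how many genes chance gives. Of 100 orders of the 6 arrays, 2 gave as many genes as the real order, the real one included, with 346 genes against at most 453 in the other orders. A random order of these arrays thus seldom gave as many. The shuffling cannot tell a change of the cells from a drift of the arrays along the series, such as one in brightness. The order with 453 genes ran nearly from the dimmest array to the brightest. Within the differentiating days, 10 of 100 orders gave as many genes, with 410 in the real order and up to 2635 in another, so for that count chance order cannot be excluded. The order with 2635 genes (days 2, 4, 1, 14, 7) was exactly that of falling array brightness, a structure of the arrays themselves. With each array centred on its median, 1 of 100 orders (the real one, 1098 genes; highest other 558) and 2 of 100 (936 genes; highest other 1025, the exact reverse of the real order) gave as many. For the contrast of conditions, 1 of 6 arrays, the proliferating one, gave as many as 144 genes when set alone against the rest (highest other 7, day 14); 6 choices are too few for a share under 0.05.

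Early transient genes were nearly all of 1 sign, with 98.4% of them higher on days 1 and 2. The spike-ins on the day 2 array were brighter by 0.74, and after each array was centred on its spike-ins 41.1% were higher, so a brighter day 2 array may account for most of the excess. A transient rise of a small set of genes stays open beside it. With centring on the median, 20 genes still had a gap over 1 upward against 7 downward, a ratio of 2.86, with the spike-ins 19 against 9, and 16 against 4 with the median and low values set to the floor.

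The median of p53 targets relative to all genes was 1.19 on day 1 and 1.80 on day 4. That of mitosis genes was 0.23 on day 1, −0.17 on day 2 and −0.68 on day 4. Among random lists matched on level, the median of the mitosis list stood at percentile 98.7 on day 1 and 0 on day 7. That of the p53 list stood at 100 on day 1. A difference in brightness shared by genes of a given level cancels in these percentiles, so the test could hardly have come out otherwise. The percentiles show that the lists moved relative to genes of similar level, and they are no separate evidence on brightness. Without the 5 genes that moved most on day 1 the p53 list remained at percentile 100, and the mitosis list without its 5 on day 7 at 0. A median hardly responds to a few members, so this outcome was nearly fixed in advance. Relative to the median gene, 21 p53 targets were higher and 4 lower on day 1. On day 7, 36 mitosis genes were lower and 2 higher, so neither shift was confined to a few members. T antigen, warmth and loss of interferon changed together, so which of them sets either course cannot be separated here, and no biological explanation was tested.

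The sample descriptions name dissected cochleas and the other labels a cell line. The highest level of the 5 globin genes measured was 6.71 (Hba-a1, day 2), and on days 7 and 14 all 5 were below the floor. Levels of different probe sets cannot be set against each other, so these values do not decide whether pieces of cochlea with their blood and vessels were used. Of the 11 erythroid genes measured, 5 were above the floor in proliferating cells and 0 are in another list, and of 17 endothelial genes 5 were above it. Interferon-response genes stood at −0.78 on day 1 and mitosis genes at −2.91 on day 14 relative to all genes, the directions that the cell line labels would give, but tissue kept in culture was not tested, so which label is right stays open.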

How the results depend on the processing

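Counts of genes moved with the scaling of the arrays, the variance prior, low values and single arrays; the floor and the spike-in centring were chosen after seeing the data, and for each shift below the cause was not tested unless stated. Over the whole course 346 genes became 1164 with quantile normalization, 1098 with median centring, 1175 with the spike-ins, 104 with the floor and 1 with no variance trend, and 212 to 485 with an array left out. The 144 genes of the contrast of conditions became 376, 384, 476, 15 (1 higher and 14 lower) and 26 in that order, and 74 to 277. The 410 within differentiating days became 1120, 936, 934, 0 (798 at an unadjusted p under 0.05) and 75, 230 among genes above the 50th percentile of mean level, where fewer genes are tested, and from 36 without day 14 to 2151 without day 1. Of the 346, 144 and 410 genes, 327, 121 and 344 also passed with median centring. Lists past camera numbered 10, 8 and 6, and 0 in each with an estimated correlation; with the floor the last count was 13. Early transient genes with a gap over 1 went from 55 to 29, 27 and 28 under the 3 scalings, to 20 with median centring and the floor together, and to 16 above the 50th percentile. The p53 list's course over time reversed to −0.19 without the proliferating array, against up to 1.95 without another array, and Stmn2's to −0.35 with its probe sets averaged. A named gene or list was counted once per comparison, 176 results in all, so it can enter more than once. Of 2532 alternative values, 2000 kept direction and side of the threshold (or, with no test, their size). These include results that passed neither in the main fit nor in the alternative. A call was lost in 477 and gained in 42, and 11 moved in size. The floor, which flattens dim genes, accounted for 98 of the losses and the untrended prior for 95. Alternatives for linear values were not run, as the values are log2. No paired analysis was possible because each group has 1 array. Signal over background limits dim genes: in simulation a log2 change of 2 was recovered for 44.7% of genes brighter than 6 over the whole course, against 22.0% overall.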

Other observations

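The B1 repeat control, a probe set for a family of short interspersed repeats, was brighter in the early differentiating days. It stood at 10.81 on the proliferating array, and relative to the median gene it was higher by 0.96 on day 1, 0.83 on day 2, 0.87 on day 4, 0.32 on day 7 and 0.40 on day 14.

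Members of 1 list did not all move 1 way. In the mesenchymal and matrix list of 47 genes, Mgp, Postn and Dcn rose between conditions (3 higher and 1 lower when adjusted over the list alone), while Tagln went from 8.72 in proliferating cells to 2.69 on day 14. In the epithelial list of 37, Itgb4 rose while Cxadr fell. Lamb3 and Krt7 were above the floor on days 1 to 4, at 7.72 and 5.50 on day 4, and below it on the other 3 arrays. The inflammatory list held Cxcl1, which rose at least 8.02-fold between conditions, and Ccl2, which fell by 1.98 ± 0.43, while Ptgs2 fell at least 7.77-fold from proliferating cells to day 14.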
